A study of Homo sapiens with 8 samples.

How the data were processed

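Total RNA of Huh-1 cells, an established human hepatocellular carcinoma line, was measured on Illumina bead arrays, on which biotin-labelled cRNA binds to probes on beads. The array type was not given in the sources used here. Per the labels, every culture was reverse-transfected with a control siRNA (siControl) or an siRNA against LSD1 (siLSD1; the gene is KDM1A) and, 48 h later, was kept in 1% O2 for 24 h. The labels give 2 biological replicates per group and 2 technical replicates of each, so that the 8 arrays stand for 4 biological samples. Every sample was hypoxic, and no culture at normal oxygen was analysed here.

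The authors deposited 2 tables. The first holds non-normalized bead intensity on a linear scale and a detection p-value for every array, with 34694 rows named by gene symbol. Per the submitters' processing notes, BeadStudio 3.1.1.0 was used. The detection p-value of each row was deposited by the authors beside the signal, without a statement of how it was computed or summarised over probes. The second, deposited by the authors as the series' value table, holds intensity on a linear scale that was made comparable between arrays. How probes were summarised to 1 row per symbol and how the second table was normalized were not given in the sources used here. Its 34687 rows are all in the first table, and 7 rows of the first table are absent from it. Each of its 8 columns correlated best with the same array of the first table, and its column medians lay between 172.7 and 172.9, against 168.2 to 180.2 in the first table. Its scale was therefore taken as linear, without centring.

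The detection p-value of a row was not a rank of that row's own signal. Of 12255 rows brighter than every ERCC control row on all 8 arrays, 761 had a detection p of 0.01 or more on all 8 arrays, and the highest signal among these was 30600.2. The normalization fixed before the data were examined was neqc, which infers the negative controls from these p-values. On this table it inferred a background SD of 799 to 1101 signal units per array, while the median ERCC row had a signal of 114. The values reported therefore come from the fallback written beside it, normexp background correction with an offset of 50 followed by quantile normalization and log2. That fallback had been written for data without detection p-values, so its use here departed from the plan. That choice was made after the gene count under neqc had been seen (0 genes under both) and before any gene list was tested under neqc. The results under neqc are given with the other alternatives, and they differ for the gene lists.

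Rows with a detection p under 0.01 on at least 4 of the 8 arrays were tested, without the 92 ERCC rows, which left 12870 genes. Because of the p-values described above, this filter also leaves out bright rows such as VEGFA, CDKN1A and PCNA, and a filter on signal was added after the data were seen (a row had to be brighter than every ERCC row on at least 4 arrays, which kept 16049 rows, 3204 of them only under this filter). Symbols were updated with the RefSeq gene table of GRCh38.p14, from which only names were used: 17762 rows carried a current symbol, 2735 matched through an older one (KDM1A is AOF2 in the tables, HILPDA is C7ORF68), 720 carried an older symbol of several genes or one that clashed with another row, and 13385 had no match and kept the name in the tables. Genes with a near-identical copy can share probes, which applies here to the metallothioneins, ADH1A with ADH1C, HP, CYP4A11, the UGT2B genes and the HLA genes; their values are uncertain in that respect.

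The technical arrays of each biological sample were averaged, and siLSD1 was compared with siControl, 2 against 2, with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Errors given after ± are the standard error of the log2 difference from that fit, unless named SD. With 2 against 2 the smallest two-sided exact permutation p is 0.333, so no single value can pass a permutation test here, and the number of arrays limits the precision of every value. The replicate numbers are shared by both groups, but nothing in the labels says that a number marks a shared day or batch, and no slide or date was given, so no block was used and no slide could be tested.

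A total of 25 gene lists was fixed before the data were examined. Lists with at least 5 tested genes, 24 of the 25, were tested with camera (preset inter-gene correlation 0.01, adjusted over the 24 lists), which asks whether the genes of a list differ more than the other genes. Camera with an estimated correlation, fry and preranked gene set enrichment with fgsea 1.28.0 (10000 permutations) were alternatives; the series' design text names gene set enrichment analysis. For each list the number of genes past the threshold is given adjusted over all genes tested and adjusted over the list alone.

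The rule for naming genes was KDM1A, then the 12 largest rises and 12 largest falls among genes past the adjusted p whose 4 siLSD1 arrays all lay on the same side of the 4 siControl arrays, without LOC and orf symbols, then up to 4 genes per list with the smallest p. No gene passed, so the 12 largest in each direction were taken, after the data were seen, from the genes that passed when all 8 arrays were fitted with the technical replicates as a random block (duplicateCorrelation). That fit was planned as an alternative and treats the biological samples as more independent information than 2 against 2.

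The fits were tested on simulated data with 200 changed genes among 12870, 5 simulations each, for the comparison of siLSD1 with siControl. With the siControl replicates spread more than the siLSD1 replicates, as measured, the fit of averaged arrays recovered 62.6% of genes changed 4-fold and 1.6% of genes changed 2-fold, and 4.75% of its calls were false. The fit with technical replicates modelled recovered 94.2% and 50.2%, but 38.2% of its calls were false. In 20 simulations camera called a list of 20 genes shifted by 0.3 on the log2 scale 19 times and called 1 of 460 unchanged lists. Genes were simulated as independent of each other, which real genes are not.

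The alternatives were no background correction, an offset of 16, neqc, median scaling, the authors' normalized values, no filter, detection on all 8 arrays, the signal filter, the replicate number as a block, the technical replicates modelled, all 8 arrays as independent samples, a 1.5-fold minimum, treat against 1.2-fold, and leaving out each biological replicate and each array. Neqc was the normalization planned as main, and it became an alternative after its gene count had been seen. The signal filter was added after the data were seen. Collapsing probes to genes did not apply, since rows were genes already.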

Results

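The deposited arrays address how depletion of LSD1, a histone demethylase encoded by KDM1A, affects gene expression in hypoxic hepatocellular carcinoma cells. Huh-1 cells treated with siControl or siLSD1 and then kept in 1% O2 for 24 h were profiled, with 2 biological replicates per group and 2 arrays of each, 8 arrays in all. Between 12447 and 13290 rows were detected per array, and the median signal was 168 to 180 on a linear scale. The 92 ERCC control rows stayed at or below a signal of 228.

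KDM1A was the first gene examined, since the siRNA targets it. Its non-normalized signal was 3920 and 3642 on the arrays of siControl biological replicate 1 and 5035 and 3998 on those of replicate 2. The siLSD1 arrays gave 1576 and 1568 for replicate 1 and 1343 and 1327 for replicate 2. After normalization the log2 level was 11.97 ± 0.24 (SD, n = 2) in siControl and 10.48 ± 0.06 (SD, n = 2) in siLSD1, a log2 difference of -1.48 ± 0.18. All 4 siLSD1 arrays lay below all 4 siControl arrays, as they did for 1575 of the 12870 genes tested, with 1662 genes the other way. The difference did not pass limma's test over all genes (adjusted p = 0.223); it passed with the technical replicates modelled (adjusted p = 0.00173).

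**Figure D1:**
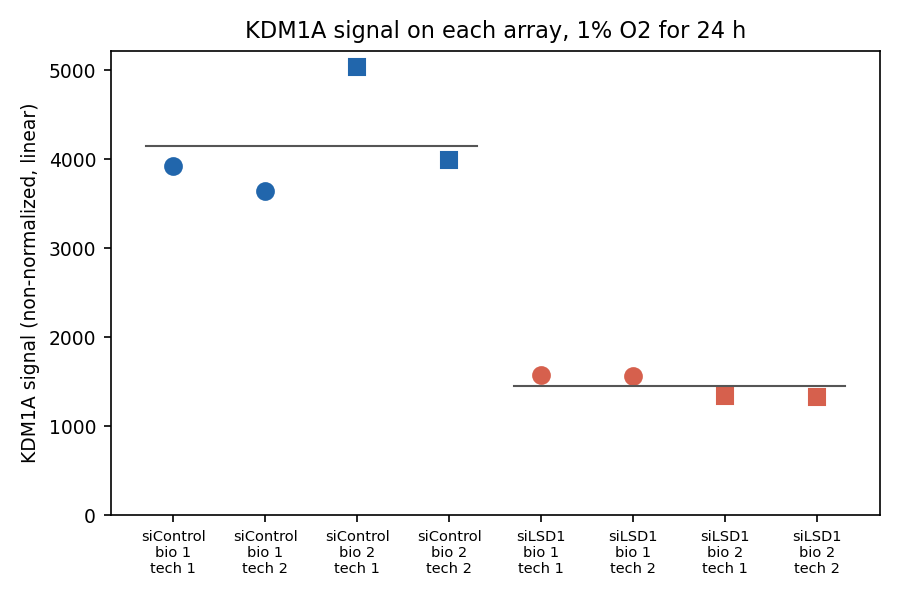
Non-normalized KDM1A signal (linear scale) on each of the 8 arrays, in blue for siControl and red for siLSD1, with circles for biological replicate 1, squares for biological replicate 2 and a grey line at the mean of each group's 4 arrays. The siLSD1 arrays lie between 1327 and 1576 and the siControl arrays between 3642 and 5035.

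The 12 largest differences in each direction were taken from the genes called with the technical replicates modelled. CYP26B1, which degrades retinoic acid, was higher in siLSD1 by 3.13 ± 0.48 on the log2 scale, the matrix protease MMP7 by 2.47 ± 0.22, and the alcohol dehydrogenases ADH1A and ADH1C by 2.41 ± 0.47 and 2.22 ± 0.31. CYP24A1, which inactivates vitamin D, was higher by 2.33 ± 0.65, haptoglobin (HP) by 1.99 ± 0.19, the growth factor gene PDGFB by 1.95 ± 0.39, the citrate transporter SLC13A5 by 1.93 ± 0.42 and the endothelin precursor EDN1 by 1.91 ± 0.42. TSPAN1, PAQR9 and PCED1B, at 2.21, 1.87 and 1.84, complete the 12 higher genes. In the other direction LOX, the collagen cross-linking lysyl oxidase, had a log2 difference of -2.59 ± 0.82, the aromatic amino acid decarboxylase DDC -2.28 ± 0.17, the water and glycerol channel AQP10 -2.02 ± 0.19, the G protein subunit GNG4 -1.91 ± 0.18 and the calcium-binding protein gene SCGN -1.73 ± 0.17. The metallothionein MT1E stood at -2.11, PAQR8 at -1.80, the kisspeptin receptor KISS1R at -1.78, the lipid droplet protein gene CIDEC at -1.66, BICDL2 at -1.62 and the interferon-inducible GTPase GBP1 at -1.58. CYP4A11, a fatty acid hydroxylase, was detected on all 4 siControl arrays and on 0 of the siLSD1 arrays. Its signals after background correction and quantile normalization were 607 and 641 for siControl replicate 1 and 220 and 201 for replicate 2. On the siLSD1 arrays these normalized signals ran from 103 to 127.

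These 24 genes did not pass limma's test over all genes (adjusted p from 0.209 to 0.356). They were named because they passed with the technical replicates modelled, a fit in which 38.2% of calls were false on simulated data with the measured spread. Several rested unequally on the controls: the LOX difference was -3.90 against siControl biological replicate 1 and -1.27 against replicate 2, and that of CYP24A1 was 3.35 and 1.31. Leaving out either siControl replicate also moved the fold of CYP26B1, ADH1A, PDGFB, SLC13A5, EDN1, MT1E, PAQR8, CIDEC and CYP4A11 by over 1.5 times. For DDC the values were -2.31 and -2.25. TSPAN1, HP, PDGFB and SLC13A5 were detected on 2 of 4 siControl arrays and PAQR8 on 1 of 4 siLSD1 arrays, so the size of their differences is uncertain.

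Across 12870 genes, limma called 0 at an adjusted p of 0.05 with 2 samples against 2, and the smallest adjusted p was 0.209. At an unadjusted p under 0.05 there were 1515 genes, 762 higher and 753 lower in siLSD1, where 644 would be expected by chance alone. The difference exceeded 2-fold for 208 genes, 107 higher and 101 lower. Both siLSD1 samples lay above both siControl samples for 2906 genes and below for 2698, together 43.5% of genes. Chance gives 33.3% for 2 samples against 2 if all samples vary alike. The log2 difference between replicates had an SD over genes of 0.50 in siControl and 0.18 in siLSD1. Both chance figures, 644 genes and 33.3%, leave this unequal spread out, so the excess over them is no measure of an siLSD1 effect. With the technical replicates modelled 375 genes were called, 186 higher and 189 lower, and with siControl biological replicate 1 or 2 left out, 2180 or 5006 genes were called, fits whose spread comes from the siLSD1 pair alone.

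The siControl replicates differed from each other far more than the siLSD1 replicates did. Their log2 difference had an SD of 0.50 over genes, with 679 genes over 2-fold apart, against 0.18 and 1 gene for siLSD1. Across genes, which are not independent replicates, the arrays of the siControl replicates correlated at r = 0.969, siControl replicate 2 with siLSD1 at 0.982 to 0.985, and the siLSD1 replicates with each other at 0.995. The siLSD1 mean was over 2-fold from siControl replicate 1 for 696 genes and from replicate 2 for 182. DNA replication genes were lower in siControl replicate 2 than in replicate 1 by a median of 0.68 on the log2 scale (-0.68), and hepatocyte genes were higher by 0.58. The plot of list medians gives each list against each siControl replicate, and the medians had opposite signs against the 2 replicates for LSD1 partners, other hypoxia-induced genes, mitosis, DNA replication, p53 targets, hepatocyte, cholesterol synthesis, fatty acid synthesis, ER and amino acid stress, coagulation and heat shock. Those of oxidative phosphorylation were -0.20 and 1.7e-05, the latter too small to give a direction.

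Glycolysis genes fell as a list in siLSD1. Of 19 tested genes 16 had lower estimates, the median log2 difference was -0.20, and camera gave an adjusted p of 0.014 over the 24 lists (adjusted p = 0.883 with an estimated correlation). The median was -0.19 against siControl replicate 1 and -0.28 against replicate 2. The aldolase ALDOC stood at -0.61 ± 0.15, phosphoglycerate mutase PGAM1 at -0.62 ± 0.18, glucose phosphate isomerase GPI at -0.42 ± 0.15, and PDK1, a kinase that inhibits pyruvate dehydrogenase, at -0.41 ± 0.15. No gene of the list passed adjusted over all genes or adjusted over the list alone. The list's adjusted p was 0.0924 with fry; it was 0.0283 with preranked enrichment, and 0.252 without siControl biological replicate 2.

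Other hypoxia-induced genes did not pass as a list, with 10 higher and 13 lower estimates (23 tested, median -0.09, adjusted p = 0.807). The lipid droplet gene HILPDA was measured at -0.73 ± 0.17 and LOX at -2.59 ± 0.82, while the oxidoreductase ERO1A stood at 0.65 ± 0.16 and the repressor BHLHE40 at 0.47 ± 0.15. Among the regulators of the HIF pathway (10 tested, median -0.01, adjusted p = 0.636), EPAS1, which encodes the HIF-2α subunit, was higher by 0.81 ± 0.16 and CITED2 by 0.54 ± 0.19. EPAS1 was the 1 regulator past the threshold adjusted over the list alone, and 0 passed adjusted over all genes.

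The interferon response list also fell. Of 12 tested genes 9 had lower estimates, with a median of -0.34 (adjusted p = 0.045; adjusted p = 0.883 with an estimated correlation), -0.30 against siControl replicate 1 and -0.28 against replicate 2. The antiviral genes IFIT2 (-0.89 ± 0.16), ISG15 (-0.67 ± 0.17), the RNA sensor IFIH1 (-0.52 ± 0.19) and IFI6 (-0.41 ± 0.17) had the smallest p. IFIT2 passed adjusted over the list alone, and 0 genes adjusted over all genes. The call depended on the setting. The adjusted p of the interferon response list was 0.000841 with no filter (25 genes) and 0.0037 with the signal filter (16 genes), but 0.0518 with fry, 0.105 with preranked enrichment, 0.151 after neqc, where the median was -0.031, 0.0552 with median scaling, 0.0537 on the authors' normalized values and 0.087 with detection on all arrays. It was 0.106 and 0.151 without siControl biological replicates 1 and 2, 0.0615 without siLSD1 biological replicate 2, 0.0559 and 0.0736 without siControl arrays 2 and 3, and 0.052 without siLSD1 array 3.

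**Figure D2:**
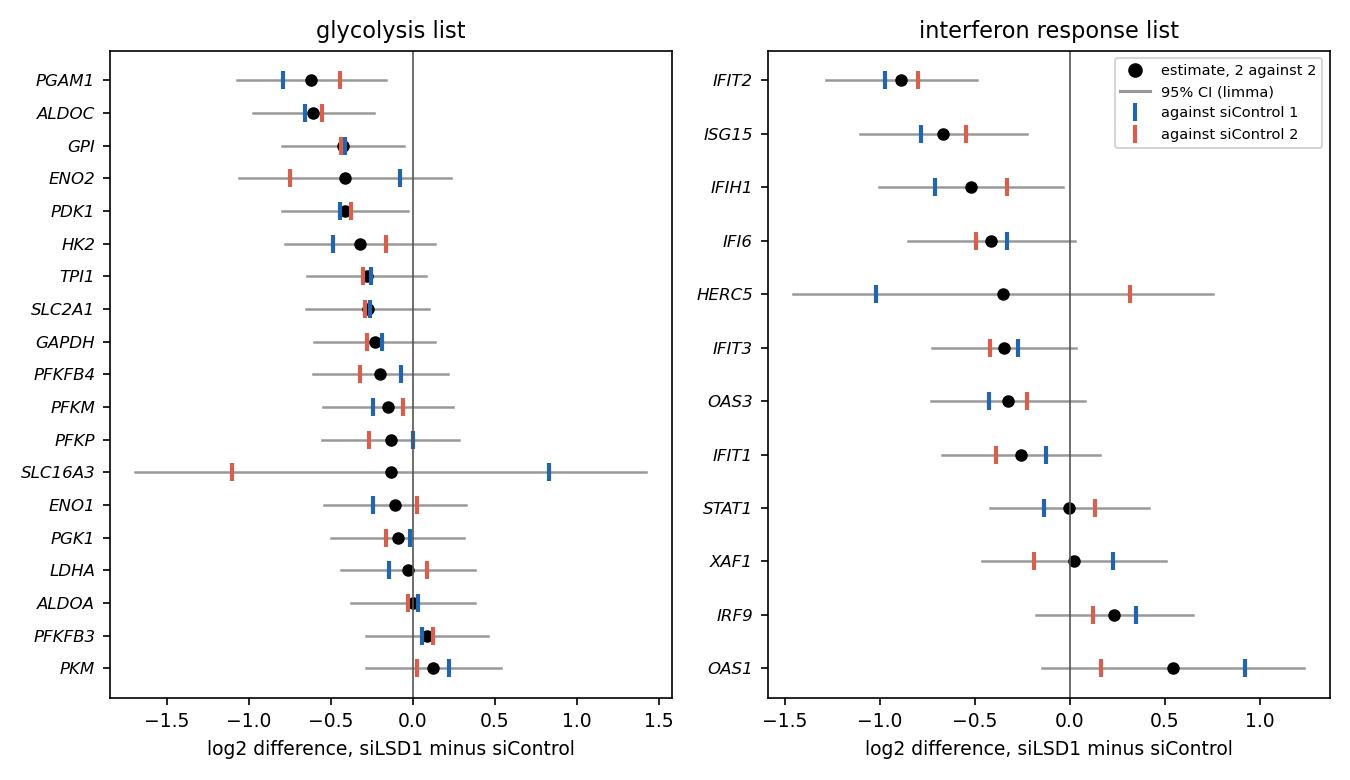
Log2 difference between siLSD1 and siControl for each tested gene of the glycolysis list (left, 19 genes) and the interferon response list (right, 12 genes), with black points for the estimates of 2 samples against 2, grey bars for their 95% confidence intervals from limma, and blue and red ticks for the difference of the siLSD1 mean from siControl biological replicates 1 and 2. Estimates lie below 0 for 16 of 19 and for 9 of 12 genes.

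Metallothioneins, the metal-binding proteins, were the third list called and the one with the largest median, -1.49 over 6 genes (adjusted p = 0.0192; adjusted p = 0.883 with an estimated correlation). MT1E stood at -2.11 ± 0.67, MT1A at -1.52 ± 0.73, MT1F at -1.45 ± 0.77 and MT2A at -1.31 ± 0.61, with MT1E and MT1F detected on 3 of 4 siLSD1 arrays, and 0 passed adjusted over all genes or over the list alone. The median was -2.67 against siControl replicate 1 and -0.29 against replicate 2, and the siControl replicates differed from each other by -2.37. The adjusted p of the metallothioneins list was 0.167 without siControl biological replicate 1, 0.151 after neqc, 0.711 with fry and 0.126 with preranked enrichment.

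**Figure D3:**
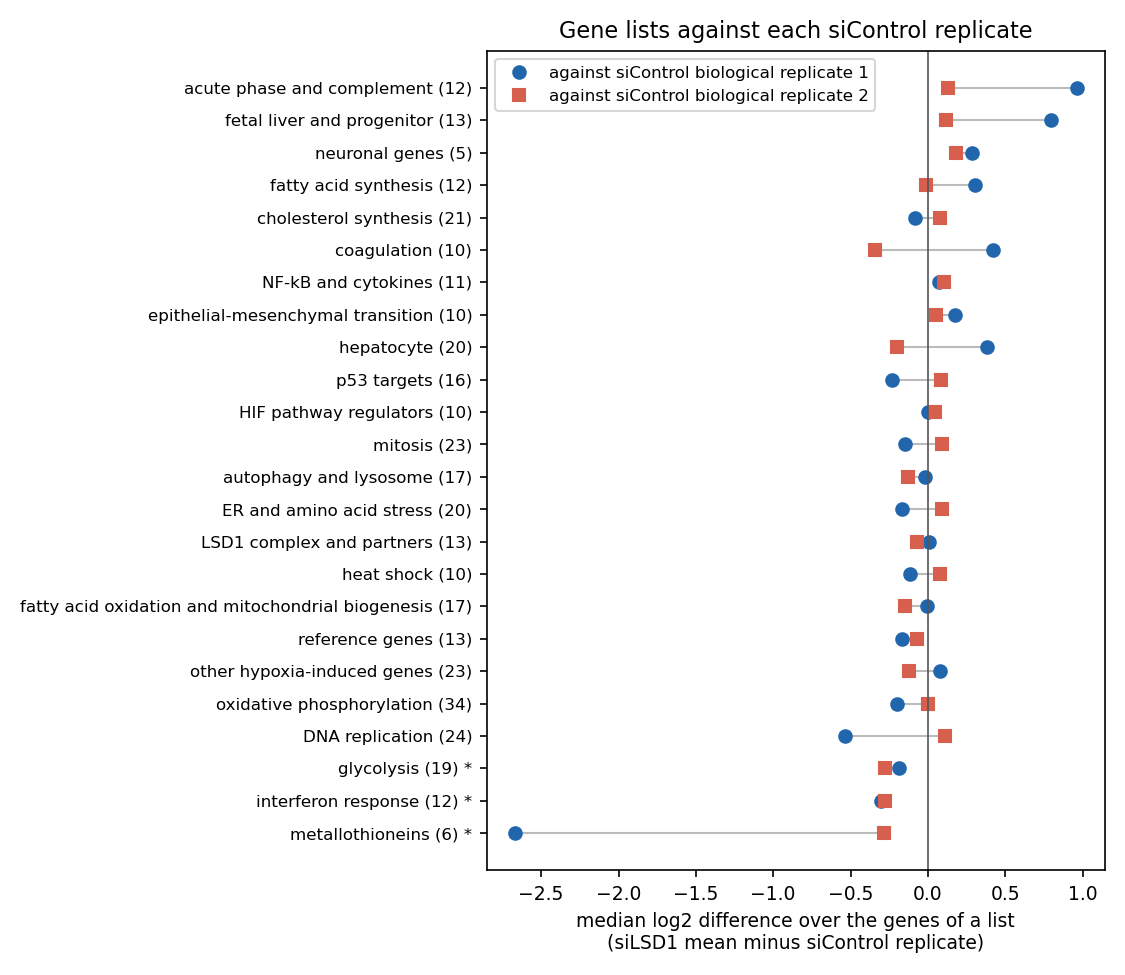
Median log2 difference of the siLSD1 mean from siControl biological replicate 1 (blue circles) and replicate 2 (red squares) for the 24 tested lists, with the number of tested genes in brackets and an asterisk where camera's adjusted p is under 0.05. Glycolysis and interferon response lie below 0 against both replicates, at -0.19 and -0.28 and at -0.30 and -0.28, while metallothioneins lie at -2.67 and -0.29.

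The liver lists did not pass, and their estimates lay higher against siControl replicate 1 than against replicate 2. The acute phase and complement list had a median of 0.59 over 12 genes (adjusted p = 0.0682), 0.96 and 0.13 against the siControl replicates. In it HP was higher by 1.99, and the protease inhibitor SERPINA3 stood at -0.70 ± 0.15; HP and SERPINA3 are the 2 genes past the threshold adjusted over the list alone. Fetal liver and progenitor genes had a median of 0.35 over 13 genes (adjusted p = 0.0682), 0.80 and 0.12 against the replicates. SALL4 was detected on 2 of 4 siControl arrays and on all 4 siLSD1 arrays. The surface markers PROM1, EPCAM and CD44 stood at 0.82 ± 0.25, 0.64 ± 0.19 and 0.53 ± 0.17, CD44 being detected on 3 of 4 siControl arrays. The hepatocyte list had a median of 0.05 over 20 genes (adjusted p = 0.636), 0.38 and -0.20 against the replicates. The coagulation list (10 genes, median 0.13, adjusted p = 0.91) likewise changed sign between the replicates, at 0.42 and -0.34, and its anticoagulant PROC, at -0.80 ± 0.17, was the 1 gene past the threshold adjusted over the list alone. Without siControl biological replicate 2 these lists all passed, with adjusted p of 6.47e-06, 0.000666, 0.00401 and 0.0353, and without siControl biological replicate 1 the coagulation list passed as lower (adjusted p = 0.0456). The acute phase and complement list and the fetal liver and progenitor list also passed without siLSD1 biological replicate 1 (adjusted p = 0.0246 and 0.0455), without siLSD1 biological replicate 2 (adjusted p = 0.036 each) and without siControl array 4 (adjusted p = 0.0484 each), the latter list without siLSD1 array 2 (adjusted p = 0.0478), and the former with no filter (adjusted p = 0.016). Both lists passed with the replicate number as a block (adjusted p = 0.0181 and 0.0374) and with the technical replicates modelled (adjusted p = 0.00257 and 0.022). With an estimated correlation, in the fit of 2 samples against 2, the adjusted p was 0.883 for each of them.

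Mitochondrial and lipid lists did not pass. Oxidative phosphorylation had a median of -0.10 over 34 genes (adjusted p = 0.16), -0.20 against siControl replicate 1 and 0.00 against replicate 2, with the complex I subunit NDUFS1 at -0.56 ± 0.21 and CYC1 at -0.43 ± 0.17. In the fatty acid oxidation and mitochondrial biogenesis list (17 genes, median -0.05, adjusted p = 0.314), HADH of the β-oxidation cycle stood at -1.08 ± 0.16 and was the 1 gene past the threshold adjusted over the list alone, and CPT1A, which admits fatty acids to mitochondria, stood at -0.52 ± 0.20. In fatty acid synthesis (12 genes, median 0.17, adjusted p = 0.807), the acetyl-CoA carboxylase ACACB stood at -1.29 ± 0.16 and the acyltransferase GPAM at 0.76 ± 0.17, and these 2 passed adjusted over the list alone. Cholesterol synthesis genes (21 genes, median 0.14, adjusted p = 0.369) had 0 genes past it, with INSIG1 at 0.63 ± 0.18 and SQLE at 0.49 ± 0.16.

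Cell division and stress lists did not pass either. DNA replication genes had a median of -0.13 over 24 genes (adjusted p = 0.176, and adjusted p = 0.883 with an estimated correlation), -0.53 and 0.11 against the siControl replicates. The DNA replication list passed as lower without siControl biological replicate 2, at a median of -0.53. In that fit the lone siControl sample is assumed to vary like the siLSD1 pair. Mitosis genes had a median of -0.01 over 23 (adjusted p = 0.692), with CENPF at 0.92 ± 0.20 and CCNB1 at 0.80 ± 0.20 but AURKA at -0.46 ± 0.16. Among p53 targets (16 genes, adjusted p = 0.807), GDF15 stood at 1.03 ± 0.22 and SESN1 at -0.78 ± 0.18. The NF-kB and cytokines list (11 genes, adjusted p = 0.776) held IER3 at 1.74 ± 0.35, the 1 gene past the threshold adjusted over the list alone, and TNFAIP3, a brake on NF-kB, at -1.39 ± 0.60 (-2.33 and -0.44 against the siControl replicates). The adjusted p was 0.807 for ER and amino acid stress, where the chaperone HSPA5 stood at 0.55 ± 0.20, 0.807 for heat shock, 0.687 for autophagy and lysosome, where the channel MCOLN1 stood at -0.90 ± 0.24, and 0.807 for epithelial-mesenchymal transition, where ITGA5 stood at -0.48 ± 0.17.

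Of the partners of LSD1 (13 genes, median -0.02, adjusted p = 0.776), HMG20B stood at -0.38 ± 0.14, RCOR2 at -0.97 ± 0.41 (-0.34 and -1.59 against the siControl replicates) and HDAC2 at 0.29 ± 0.15, and KDM1A itself was the 1 gene past the threshold adjusted over the list alone. Neuronal genes, a class that LSD1 complexes silence in other cells, had 5 tested members of 23, a median of 0.22 and an adjusted p of 0.176 (0.0157 with the technical replicates modelled, and an adjusted p of 0.883 with an estimated correlation in the fit of 2 against 2). The tubulin TUBB3 stood at 1.24 ± 0.24 and the synaptic SNAP25 at 0.94 ± 0.18, both past the threshold adjusted over the list alone. Estimates were higher for 4 of these genes and lower for 1, CPLX1, at -0.37 ± 0.14. All 4 siLSD1 arrays lay below all 4 siControl arrays for CPLX1, which was detected on 2 of 4 siLSD1 arrays. Of 15 markers of other cell types 3 were tested, CD68 at -0.28 ± 0.19, LUM at -0.13 ± 0.19 and LYZ, detected on 2 of 4 siControl arrays, at 0.02 ± 0.17. The reference genes had a median of -0.06 over 13 (adjusted p = 0.604). Median, mean and camera's direction did not share a sign for HIF pathway regulators, mitosis, p53 targets, fatty acid synthesis, ER and amino acid stress, NF-kB and cytokines, and coagulation. Camera's direction turned when siControl biological replicate 1 was left out for DNA replication, p53 targets, hepatocyte, fatty acid synthesis and heat shock, and when replicate 2 was left out for the LSD1 partners, other hypoxia-induced genes, mitosis, ER and amino acid stress, NF-kB and cytokines, and coagulation.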

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

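The tests of the siControl replicates, of the glycolysis list against each siControl replicate, of the metallothioneins and of the number of lists under other splits were chosen after the result was seen; those of brightness and of the number of genes under other splits were written before.

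Single arrays stood apart in 6 of 290 groups of 4 arrays. Chance gives about 1 in 20 for independent samples, or 14.5 of the 290 groups, more than the 6 found. These arrays, technical pairs of 2 biological samples, are not independent. HMG20B was at a log2 level of 10.12 on siLSD1 array 1 and between 10.17 and 10.17 on the others; NDUFS1 was at 7.71 on the same array, the others between 7.52 and 7.54. HSPE1 was at 12.66 on siControl array 2, the others between 12.89 and 12.91. The median of the mitosis list was 10.72 on siLSD1 array 2, against 10.81 to 10.82, that of fatty acid synthesis 10.97 on siControl array 3, against 10.85 to 10.87, and that of NF-kB and cytokines 10.03 on siLSD1 array 1, against 10.11 to 10.13.

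The siControl replicates differed over 2-fold for 679 genes, against 1 gene for siLSD1. The tables argue against a failed array, since the 2 arrays of replicate 1 differed with an SD of 0.155 over genes, as did those of the other samples (up to 0.155), and against an exchange with siLSD1, since the lowest KDM1A value of replicate 1 lay 1.21 above the highest siLSD1 array on the log2 scale. A different state of the cultures, such as growth or confluence, may account for it: 20 of the 24 lists differed by over 0.1 in median between the siControl replicates. No label or further culture decides this, and RNA quality and an exchange with a sample outside the series also stay open.

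The glycolysis list was lower in siLSD1, and siControl replicate 1 alone does not account for it, since the median against replicate 2 was -0.28. Nor does the brightness of these genes, since 0.050% of 10000 random lists matched on mean level had a median as low. The call did depend on siControl replicate 2: without it the median was -0.19 and the list was not called. In both other splits of the 4 samples into pairs the list's median was 0.01, and camera's adjusted p was 0.884 and 0.477. An effect of LSD1 depletion, an effect of this siRNA on other transcripts, and a difference between cultures that happened to follow the groups may each be the cause, and with 1 siRNA and 2 cultures per group they were not tested.

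The metallothioneins behaved differently. Without siControl biological replicate 1 the adjusted p was 0.167 and the median moved from -1.49 to -0.29, and both other splits of the samples also called the list, with adjusted p of 0.0195 and 0.000507. The high level in siControl replicate 1 is therefore a candidate explanation for most of the difference between the groups; why that sample was high was not tested.

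Only 3 splits of the 4 biological samples into pairs exist, too few to give a share under 0.05. The real split gave 1515 genes at an unadjusted p under 0.05 and the highest other split 262, so that 1 of 3 splits gave as many. Both other splits part the siLSD1 replicates, the samples closest to each other (r = 0.995), which adds spread within their groups. Their lower gene counts therefore cannot decide whether the groups differ. The real split gave 3 lists past the adjusted p and each other split 7, so that 3 of 3 gave as many, with DNA replication and metallothioneins among the lists of both other splits. Both other splits set the siControl replicates on opposite sides, so the difference between these replicates enters them. With the side of siControl replicate 2 minus the other, their medians were -0.35 and -0.35 for DNA replication and -1.11 and -1.27 for metallothioneins. Replicate 2 minus 1 was -0.68 and -2.37 for these lists in siControl, and 0.03 and 0.06 in siLSD1. A difference between control cultures can thus bring camera with the preset correlation to call more lists than the real split. Why the siControl replicates differed was not tested.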

How the results depend on the processing

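Neqc, planned as the main normalization, was made an alternative after its gene count had been seen, and the signal filter was added after seeing the data. Limma called 0 genes in every alternative that kept 2 averaged samples per group (background correction, scaling, filters, the replicate block, the fold limits), with 1515 genes at an unadjusted p under 0.05 in the reported setting. It called 375 with the technical replicates modelled and 2221 with all 8 arrays as independent samples, which counts technical arrays as biological ones; KDM1A then passed at -1.48 (adjusted p = 0.00173 and 0.000136). Leaving out replicates or arrays gave 0 to 5006 genes, with KDM1A between -1.66 and -1.31. The counts of 5006 and 2180 came without siControl biological replicate 2 or 1, where the lone siControl sample is assumed to vary like the siLSD1 pair. The filters set which genes could be tested: 12870 passed the filter on detection, which is not a filter on signal here, 16049 that on signal and 10594 detection on all arrays.

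The number of called lists was 3 as reported, 1 after neqc, 1 with detection on all arrays, 6 with the technical replicates modelled (acute phase and complement, fetal liver and progenitor, and neuronal genes in addition), 0 with an estimated correlation, 0 with fry and 1 with preranked enrichment (glycolysis). The glycolysis list, -0.20, was not called with an estimated correlation, with fry or without siControl biological replicate 2; over its alternatives the adjusted p ran from 0.000307 (neqc) to 0.883. The interferon response list was not called after neqc (-0.031), with median scaling (-0.31), on the authors' normalized values (-0.28), with detection on all arrays (-0.47), or, at -0.34, with an estimated correlation, fry and preranked enrichment. The metallothioneins list was not called after neqc (-1.19) or, at -1.49, with an estimated correlation, fry and preranked enrichment; with detection on all arrays it had under 5 genes. Over the left-out samples 2 to 6 lists were called, and the medians were -0.28 to -0.19 for the glycolysis list, -0.35 to -0.28 for the interferon response list and -2.67 to -0.29 for the metallothioneins list. Over their alternatives the adjusted p ran from 0.000841 to 0.883 for the interferon response list and from 9.43e-17 to 0.883 for the metallothioneins list. The cause was not tested.

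With the replicate block 0 genes and 5 lists were called (acute phase and complement, and fetal liver and progenitor, in addition). The replicate numbers were not taken as pairing the samples, since there are 2 pairs and no label says so; the replicate differences of both groups correlated at 0.115 over genes.

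None of the lists and genes that reversed was called as reported, and the coagulation list without siControl biological replicate 2 was the only one past the threshold in its reversed direction (adjusted p = 0.0353). The cause was not tested. Camera's direction reversed for the p53 targets list after neqc (median 0.0043), for the NF-kB and cytokines list with no filter (-0.065) and the signal filter (-0.36), for the ER and amino acid stress list (-0.014) and the coagulation list (0.13) with the block, for the coagulation list (0.13) and the fatty acid synthesis list (0.17) with technical replicates modelled, and for the latter with fry and preranked enrichment (0.17). Over the left-out samples the ranges that include a reversal were -0.78 to 0.35 for HSPH1, -0.30 to 0.030 for LUM, -0.13 to 0.18 for LYZ, and for the lists -0.071 to 0.12 for LSD1 complex and partners, -0.12 to 0.076 for other hypoxia-induced genes, -0.15 to 0.093 for mitosis, -0.53 to 0.11 for DNA replication, -0.23 to 0.085 for p53 targets, -0.20 to 0.38 for hepatocyte, -0.015 to 0.31 for fatty acid synthesis, -0.17 to 0.089 for ER and amino acid stress, 0.016 to 0.15 for NF-kB and cytokines, -0.34 to 0.42 for coagulation and -0.11 to 0.080 for heat shock. Of the 118 named genes besides KDM1A, 93 passed the test with arrays as independent samples and 37 with technical replicates modelled; none passed in the alternatives of background correction, scaling, filter or block, where detection on all arrays left 104 of them. Without siControl biological replicates 1 and 2, 69 and 96 passed.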

Other observations

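The gene families, and the retinoid and antigen presentation lists, were chosen after the results for the fixed lists had been seen; the outcome expected for those 2 lists was written before they were tested.

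Of 23 families defined by gene symbol, 5 passed camera at an adjusted p of 0.0424 each, and 0 passed with an estimated correlation (adjusted p = 0.96 each). The HLA genes, which present peptides to T cells, had a median log2 difference of -0.32 over 12 genes, -0.43 and -0.33 against siControl replicates 1 and 2, with HLA-B at -0.74 ± 0.15 and HLA-F at -0.55 ± 0.14, while HLA-DMB stood at 0.46 ± 0.16. The apolipoproteins had a median of 0.63 over 9 genes, 0.92 and 0.17 against the replicates, with APOH at 1.33 ± 0.18, APOC2 at 0.76 ± 0.23 and APOE at 0.66 ± 0.22. The UDP-glucuronosyltransferases, which conjugate bile acids, steroids and drugs, had a median of 0.67 over 9 genes, 1.51 and 0.15 against the replicates, and UGT2B4 stood at 1.37 ± 0.62. Histones had a median of 0.22 over 28 genes, 0.33 and 0.10 against the replicates, with H3-3B at 0.67 ± 0.18. The proteasome subunits had a median of -0.15 over 36 genes, -0.31 and 0.02 against the replicates. Over 6 ways of scaling and background correction the medians of these 5 families kept their sign. They ran from -0.33 to -0.073 for the HLA genes and from 0.031 to 0.23 for the histones, each smallest under neqc, from 0.33 to 0.89 for the UDP-glucuronosyltransferases, from 0.63 to 0.65 for the apolipoproteins and from -0.16 to -0.11 for the proteasome.

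Several bright genes of the fixed lists lay outside the main test because of their detection p-values and were chosen here after their values were seen. With the signal filter the integrin ITGB1 stood at 0.95 ± 0.21, the fibrinogen chain FGG at 1.04 ± 0.30, the interferon regulator IRF7 at -0.76 ± 0.16, the phosphofructokinase PFKL at -0.69 ± 0.16 and NFKB2 at -1.04 ± 0.29. VEGFA stood at 0.19 ± 0.15. None of these passed limma's test (adjusted p from 0.259 to 0.72).

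A hypothesis from the HLA values was that other antigen presentation genes would be lower in siLSD1 as well. The list of 17 such genes, 9 of them tested, had a median of -0.29, -0.28 and -0.26 against the siControl replicates, and an adjusted p of 0.01003 over the 2 added lists (0.2 with an estimated correlation). The transporter subunit TAP1 stood at -0.80 ± 0.19 and the immunoproteasome subunits PSMB9 and PSMB10 at -0.76 ± 0.16 and -0.72 ± 0.18, whereas RFX5, an activator of HLA class II genes, stood at 0.73 ± 0.23. The outcome met what had been expected, but the list was chosen after the lower HLA and interferon response values had been seen. It was tested on the same samples, so the outcome is no independent test of the hypothesis. The adjustment also leaves out the fixed lists and the families tested before. The result rests on few genes as well. Without the 3 proteasome genes, which had already counted in the proteasome family, the median of the remaining 6 was -0.14 with an unadjusted camera p of 0.218.

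A hypothesis from CYP26B1 and the alcohol dehydrogenases was that retinoic acid response genes would be higher in siLSD1. The list of 20 genes, 10 of them tested, had a median of 0.18, 0.22 and 0.09 against the siControl replicates, but an adjusted p of 0.308. RDH10, which makes retinaldehyde, stood at 0.49 ± 0.17, RARB at 0.24 ± 0.16 and CYP26A1 at 0.36 ± 0.22, while the retinoid-induced PLAAT4 stood at -0.79 ± 0.17. The test left the hypothesis open.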
